A study of Mus musculus with 22 samples.

How the data were processed

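Messenger RNA was measured in 22 mouse libraries of 9 groups. The cultured cells were embryonic stem cells (ESC), trophoblast stem cells (TSC), and TSC carrying a doxycycline-driven short hairpin RNA. That hairpin was directed against LacZ (shCont) or against P150, the large subunit of the histone chaperone CAF-1, which the gene Chaf1a encodes (shP150). Each of these cell groups had n = 2 libraries. The embryos were late 2-cell embryos, with 5 embryos pooled per library. They were made by in vitro fertilisation (IVF, n = 3), or by nuclear transfer from TSC (TSC clones, n = 3), from TSC with injected mRNA of the H3K9me3 demethylase Kdm4d (Kdm4d clones, n = 3), from shCont TSC (shCont clones, n = 3) or from shP150 TSC (shP150 clones, n = 2). Per the labels, the sequenced hairpin TSC were given doxycycline at 2 µg/ml for 2 days. No dose is listed for the embryo libraries, so whether P150 was lowered in the donor cells is not known from these data. Per the labels, the hairpin lines came from a C57BL/6 and JF1 cross, and the ESC and TSC lines from a C57BL/6 and DBA/2 cross. The source name of the ESC libraries reads as trophoblast stem cell, and their group was taken from title and cell type. The labels call the libraries biological replicates but do not say whether they came from separate cultures, clutches or days. If they did not, the p-values measure only the spread between these samples.

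Per the labels' protocols, cell libraries were made with a stranded mRNA kit and read as 100 bp pairs, and embryo libraries with a full-length cDNA amplification kit that does not mark strand and read as 75 bp single ends. The labels name Trimmomatic 0.36, HISAT2, featureCounts and StringTie and the mm10 build, and give no version for the latter 3. The authors deposited whole-number gene counts for the shCont and shP150 TSC, per the file header and the values. Total counts of these libraries were 19481882 and 22224825 for shCont TSC and 16952876 and 20912268 for shP150 TSC. The authors also deposited TPM (transcript abundance scaled to a fixed total per library) for these cells, for ESC and TSC, and for the embryos, per the file headers. The cell tables held 24421 genes and those of the embryos 24454. TPM keeps no read depth, so the depth and the counting error of the ESC, TSC and embryo libraries are unknown. A gene at TPM 0 is described as listed at 0, and no fold is given against a group listed at 0. Whether featureCounts used strand is not stated, so overlapping and antisense genes may share reads.

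The tests, filters, comparisons, 22 gene lists with 576 members, alternatives and the rule for naming genes were chosen before the data were examined. For shP150 against shCont TSC, counts were tested with edgeR 4.0.16 (quasi-likelihood test, TMM normalization, filterByExpr) in R 4.3.3, and the common dispersion was 0.00997. TSC were compared with ESC, and embryo groups with each other, by limma 3.58.1 with trend on log2(TPM + 1), over genes with TPM of at least 1 in at least 2 libraries. All 14 embryo libraries entered a single fit with 9 residual and 6.11 prior degrees of freedom, from which 8 comparisons were drawn. The ESC and TSC fit had 2 residual and 4.16 prior degrees of freedom. Fold changes on this scale understate the change of genes with low TPM. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, over all genes tested in that comparison, and only called genes are said to have risen or fallen. Every p-value of a gene is from edgeR or limma and is two-sided.

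Gene lists were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with all other tested genes, and adjusted over the lists of a comparison. Lists needed at least 3 tested members. The lists were pluripotency factors, trophoblast stem cell factors, trophoblast differentiation genes, 2-cell stage genes, zygotic ribosome biogenesis and RNA processing genes, maternal oocyte transcripts, the Obox homeobox family, H3K9 methylation and heterochromatin factors, histone chaperones, histone H3 genes, imprinted genes, non-canonical H3K27me3-imprinted genes, p53 target genes, DNA replication genes, mitotic cell cycle genes, germline genes, interferon-stimulated genes, heat shock and unfolded protein response genes, fibroblast (feeder) markers, primitive endoderm markers, cumulus cell markers, and Xist with Y-linked genes. The same lists were tested with a correlation estimated from the data, where camera uses only the residual degrees of freedom, few in the cell fits. They were also tested with fry, which asks whether a list changed at all rather than against other genes. For the fixed lists, fry is given only in the comparisons of cultured cells. Counts of called members are given over all genes and adjusted over the list alone. Sets taken from the data were tested the same way, and chromosome X genes among those with a known chromosome. Gene positions came from a RefSeq annotation of GRCm38.p6, the same assembly as mm10, in which 95.4% of the tested embryo symbols had a chromosome.

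The genes named were, for each of 5 main comparisons, the targets Chaf1a and Kdm4d, the 5 risen and 5 fallen genes with the largest log2 fold change, and up to 4 called members of each list with the smallest adjusted p, or its first member where none was called. The 5 risen and 5 fallen genes had to be called, with libraries that did not overlap between groups and a mean TPM of at least 5 in the higher group. Predicted genes with Gm, Rik or pseudogene symbols were left out of those. Xist and Chaf1a were followed in every embryo comparison. Genes named outside this rule are said to be.

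Alternatives were DESeq2 1.42.0, RLE size factors, no filter, a TPM minimum of 5, limma on the TPM of the hairpin lines, a pseudocount of 0.1, TPM rescaled by median-of-ratios factors, only the compared groups in the fit, the replicate number as a block, and each library left out in turn. Where that left a single library in a group, it was assumed to vary like the others. No column was left out. The scripts were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. With counts simulated for shP150 against shCont TSC, 83.7% of the tested 2-fold and 97.9% of the tested 4-fold changes were recovered. For the limma fits, values were first drawn with each gene's raw residual SD. That recovered 0% and 0% for TSC against ESC, 47% and 88% for TSC clones against IVF embryos, 44% and 94% for Kdm4d against TSC clones, and 37% and 83% for shP150 against shCont clones. After these results were seen, draws with the moderated SD were added, which recovered 24% and 94%, 53% and 95%, 53% and 97%, and 42% and 97% in the same order. Only the simulation was changed. Of the unchanged genes, at most 0.159% were called in any of these simulations. As a share of all calls, however, false calls exceeded 0.05 in some of them. For shP150 against shCont TSC, 21 unchanged genes were called beside 82 recovered 2-fold and 95 recovered 4-fold changes. For shP150 against shCont clones these were 14, 37 and 83 with the raw SD, and 7, 42 and 97 with the moderated SD. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.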

Results

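The comparisons addressed how TSC with a hairpin against P150 differ from TSC with a control hairpin, and how far TSC-cloned 2-cell embryos with injected Kdm4d mRNA, or with that hairpin in the donor cell, lie towards IVF embryos. Expression of the targeted gene was looked at first. Chaf1a, which encodes P150 (chromosome 17:56040416-56068026), had a TPM of 26.0 ± 0.199 in shP150 TSC and 87.2 ± 6.09 in shCont TSC (mean ± SD, n = 2 each). Its level was 90.1 ± 5.44 TPM in TSC and 79.7 ± 11.8 in ESC. Kdm4d (chromosome 9:14462548-14500522) was at 6691 ± 3543 TPM in Kdm4d clones and at 2.18 ± 1.18 in TSC clones (n = 3 each), a value that counts injected and embryonic transcripts together. In the 5 embryo groups, Chaf1a did not differ in any comparison by limma. It was at 37.9 ± 7.67 TPM in shP150 clones (n = 2) and 46.7 ± 17.5 in shCont clones (n = 3), with a log2 fold change of -0.24 ± 0.31 (SE) and an adjusted p of 0.798.

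TSC with the P150 hairpin differed from those with the control hairpin in 1530 of the 13407 genes tested. In shP150 TSC, 1114 genes rose and 416 fell against shCont TSC by edgeR's quasi-likelihood test (n = 2 per group). At least 2-fold changes were seen for 595 risen and 31 fallen genes. Chaf1a itself fell by 1.73 ± 0.12 on the log2 scale (SE, adjusted p 1.43e-07). Without shCont replicate 1 the count of called genes was 791 (669 risen, 122 fallen), without shCont replicate 2 it was 946 (728 and 218), and without shP150 replicate 1 it was 2356 (1295 and 1061).

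Pou5f1, the pluripotency factor that TSC normally silence (chromosome 17:35506032-35510777), had the largest log2 fold change of the genes named by the rule in shP150 TSC, 4.61 ± 0.40 (SE, adjusted p 1.63e-06). Its TPM was 8.51 ± 1.29 in shP150 TSC and 0.335 ± 0.00783 in shCont TSC, against 1605 ± 291 in ESC. The glutathione peroxidase gene Gpx2 rose by 4.28 ± 0.36 and the retinol dehydrogenase gene Adh7 by 4.09 ± 0.29. Rbp2, a retinol-binding protein gene, rose by 3.94 ± 0.43, and the histone H2B gene Hist3h2ba by 4.12 ± 0.59. Beside Chaf1a, the fallen genes with the largest change were Sox2, Klhl36, Duox2 and Zfp808. Sox2, which TSC and ESC need for self-renewal, fell from 114 ± 22.8 to 41.0 ± 13.9 TPM (adjusted p 3.24e-05). Duox2, an oxidase gene active in TSC, fell from 66.4 ± 8.17 to 26.6 ± 4.29 TPM (adjusted p 9.77e-06). Zfp808, a zinc finger gene, had a log2 fold change of -1.29 ± 0.19. Klhl36, a ubiquitin ligase adaptor gene, had one of -1.42 ± 0.29, and its adjusted p of 0.00437 became 0.0836 without shCont replicate 1.

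Among the lists in shP150 TSC, ribosome biogenesis genes were lower than other genes and fibroblast markers higher. Of 43 ribosome biogenesis genes, 6 fell and 0 rose over all genes tested, and 6 fell adjusted over the list alone (median log2 fold change -0.27, adjusted camera p 6.55e-07). The adjusted p was 0.414 with the estimated correlation. The ribosomal RNA processing gene Utp20 fell by 0.52 ± 0.12, with an adjusted p of 0.0112 that became 0.0531 without shCont replicate 1 and 0.184 without shCont replicate 2. Of 16 fibroblast markers, 6 rose, and 6 adjusted over the list alone (adjusted camera p 8.46e-05). That p was 0.414 with the estimated correlation. The surface protein gene Thy1 rose by 3.76 ± 0.32, from 0.647 to 9.65 TPM, and the fibrillin gene Fbn1 by 1.74 ± 0.23, from 0.391 to 1.74 TPM. Cumulus cell markers had 2 risen of 7 members (3 adjusted over the list alone, adjusted camera p 0.0130), 2-cell stage genes 2 of 3 (2, 0.0218) and maternal oocyte transcripts 2 of 12 (2, 0.0218). Histone chaperones had 1 fallen member of 21, Chaf1a itself (1, 0.0218). None of these calls held with the estimated correlation, where their p was 0.414, and 0.630 for the chaperones. With fry, the adjusted p was 0.0325 for ribosome biogenesis genes, 0.0304 for cumulus cell markers and 0.00443 for 2-cell stage genes. It was 0.162 for fibroblast markers, 0.144 for maternal oocyte transcripts and 0.216 for histone chaperones. The growth factor gene Areg of the cumulus list rose by 3.16 ± 0.27. Ddit4l, an mTOR inhibitor gene of the 2-cell list, rose from 5.61 to 10.4 TPM, and Uchl1, an oocyte and neuronal ubiquitin hydrolase gene of the maternal list, by 3.43 ± 0.18. Only 3 of 42 2-cell, 12 of 41 maternal and 7 of 21 cumulus list members had enough counts to be tested. The summed TPM of the 2-cell list was 6.82 ± 0.238 in shCont TSC and 13.2 ± 1.10 in shP150 TSC (SD), mostly from Ddit4l.

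Pluripotency factors split in shP150 TSC. Of 18 tested, 5 rose and 3 fell (5 and 4 adjusted over the list alone, adjusted camera p 0.483). Klf4 rose by 1.17 ± 0.15 and Spp1, a secreted phosphoprotein gene, by 2.81 ± 0.40. Of 25 trophoblast stem cell factors, 2 rose and 6 fell (2 and 6, adjusted camera p 0.161), and the lineage factor Cdx2 fell from 63.7 ± 0.361 to 38.0 ± 2.69 TPM. Of 27 H3K9 methylation factors, 5 rose and 1 fell (5 and 1, adjusted camera p 0.961), where median and mean differed in sign. The DNA methylation cofactor gene Dnmt3l rose from 14.4 ± 5.48 to 57.5 ± 7.61 TPM, and the H3K9 demethylase gene Kdm3a from 14.7 to 27.8 TPM. The histone H3.3 gene H3f3b rose from 646 ± 4.59 to 1702 ± 249 TPM. The cell cycle inhibitor gene Cdkn1a, a p53 target, rose from 105 to 199 TPM, in a list of 23 with 2 risen (5 adjusted over the list alone, adjusted camera p 0.112). No DNA replication gene of 30 and no mitotic gene of 22 was called by edgeR, with 0 adjusted over the list alone.

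TSC and ESC differed in 3675 of 13193 genes, 1401 higher and 2274 lower in TSC (limma, n = 2 per group). Called differences of at least 2-fold numbered 1241 higher and 2144 lower genes. Elf5, the factor that sustains the trophoblast lineage, was at 417 ± 19.2 TPM in TSC and listed at 0 in ESC, as were the oxidase maturation gene Duoxa2 (133 ± 2.37 TPM in TSC) and the membrane protein gene Tmem114 (112 ± 3.77). Duox2 was higher by 7.11 ± 0.27 (SE, log2) and the imprinted noncoding RNA H19 by 6.90 ± 0.38. Pou5f1 was at 1605 ± 291 TPM in ESC and listed at 0 in TSC, as were the signalling coreceptor gene Tdgf1 (1322 ± 205) and the threonine dehydrogenase gene Tdh (444 ± 110). Dppa5a, an RNA-binding protein gene of pluripotent cells, fell by 11.80 ± 0.32 in TSC against ESC and Spp1 fell by 8.77 ± 0.34. Chaf1a had a log2 fold change of 0.18 ± 0.22 (adjusted p 0.591). Which direction held more genes changed with the library left out: without ESC replicate 1, 2108 were higher and 1879 lower in TSC, and without ESC replicate 2, 1689 and 1441. Without TSC replicate 2 the count of called genes was 1875 (632 and 1243), and without TSC replicate 1 it was 1900 (604 and 1296).

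Of 25 trophoblast stem cell factors, 20 were higher and 2 lower in TSC (21 and 3 adjusted over the list alone, adjusted camera p 2.24e-11, 0.336 with the estimated correlation). Cdx2 was at 112 ± 17.3 TPM in TSC and 0.853 ± 0.112 in ESC. Of 25 pluripotency factors, 18 were lower and 2 higher (18 and 4, adjusted camera p 1.50e-08, 0.336 with the estimated correlation), with Nanog at 0.736 ± 0.00421 TPM in TSC and 682 ± 133 in ESC. Of 25 2-cell stage genes, 24 were lower (25, adjusted camera p 1.04e-09), of 29 germline genes 22 (23, 2.62e-08), of 15 maternal oocyte transcripts 9 (11, 4.40e-05) and of 9 fibroblast markers 6 (8, 0.00273). With the estimated correlation these adjusted p were 0.623, 0.611, 0.336 and 0.336. Trophoblast differentiation genes had 7 higher and 1 lower of 13 (7 and 1, adjusted camera p 0.00486, 0.336 with the estimated correlation), with the transcription factor gene Hand1 at 78.4 ± 7.96 against 0.261 ± 0.141 TPM. Ribosome biogenesis genes had 1 higher and 1 lower of 43 (0 and 0, adjusted camera p 0.00975, 0.912 with the estimated correlation). With fry, the adjusted p was 0.0110 for trophoblast stem cell factors, 0.00723 for pluripotency factors and 0.0176 for trophoblast differentiation genes. It was 0.00723 for maternal oocyte transcripts, 0.0425 for germline genes, 0.0963 for 2-cell stage genes and 0.557 for ribosome biogenesis genes. Dnmt3l was at 10.0 ± 0.885 TPM in TSC and 304 ± 4.80 in ESC, and the DNA methyltransferase gene Dnmt3b at 289 ± 25.8 and 54.5 ± 0.425. The imprinted polycomb gene Sfmbt2 was at 200 ± 27.4 TPM in TSC and 4.46 ± 1.57 in ESC.

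The 14 embryo libraries ordered by group on the first principal component, which held 47.6% of the variance and the second 11.8%. IVF libraries lay between -98.2 and -82.2, Kdm4d clones between -36.8 and -23.9, shP150 clones at 3.46 and 16.4, shCont clones between 31.9 and 48.5, and TSC clones between 63.5 and 95.6. The number of genes with TPM of at least 1 was 11563 ± 164 in IVF embryos and 14009 ± 145 in TSC clones (SD, n = 3 each). It was 12421 ± 52 in Kdm4d clones, 13551 ± 116 in shCont clones (n = 3 each) and 13426 ± 271 in shP150 clones (n = 2). Correlations between single libraries, taken across genes, which are not independent replicates, averaged 0.848 between those of IVF embryos and of TSC clones and 0.946 between those of IVF embryos and of Kdm4d clones. With IVF libraries they averaged 0.893 for shCont clones and 0.918 for shP150 clones.

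**Figure D1:**
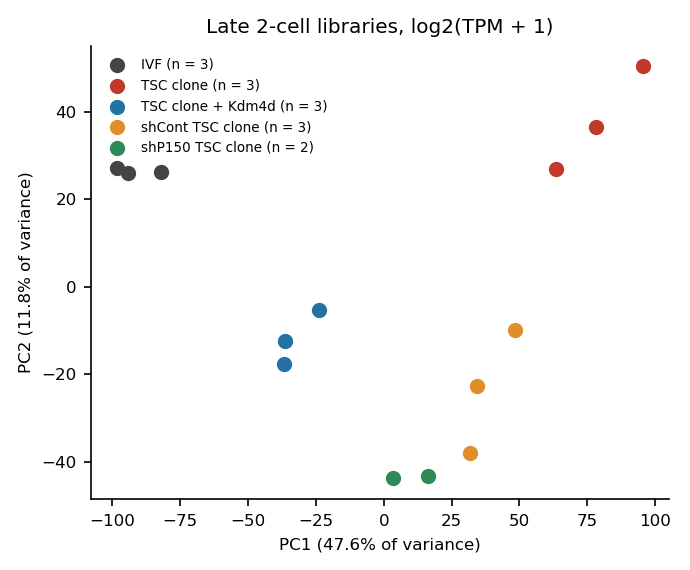
Scores of the 14 embryo libraries on the first (47.6% of variance) and second (11.8%) principal component of log2(TPM + 1), with a point per library coloured by group. The groups separate along the first component, with IVF embryos at -98.2 to -82.2 and TSC clones at 63.5 to 95.6.

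TSC clones differed from IVF embryos in 9173 of 16035 genes. Of these, 6525 rose and 2648 fell in TSC clones (limma, n = 3 per group), and 5101 and 1933 did so by at least 2-fold. TPM of a library sum to a fixed total, so these are changes of share. With TPM rescaled by median-of-ratios factors, 4216 rose and 3739 fell, and the median log2 fold change of all genes went from 0.587 to 0.243. The same rescaling moved that median from -0.382 to -0.168 for Kdm4d against TSC clones, from 0.392 to 0.173 for shCont clones, from 0.159 to 0.0108 for Kdm4d clones and from 0.362 to 0.12 for shP150 clones against IVF embryos, and from -0.142 to 0.000103 for shCont against TSC clones.

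Obox3, an oocyte-specific homeobox gene active at genome activation (chromosome 7:15625306-15639777), had the largest fall of the genes named by the rule in TSC clones. Its TPM was 8.23 ± 3.44 in TSC clones and 1221 ± 127 in IVF embryos, a log2 fold change of -7.11 ± 0.35 (SE, adjusted p 4.94e-09). Sva, a secretory antigen gene, fell by 6.81 ± 0.61, and Rfpl4b, an oocyte and embryo ring finger gene, fell by 6.23 ± 0.45. The uncharacterised genes BC147527 and AF067061, which lie near Tcstv3 on chromosome 13, had log2 fold changes of -6.78 ± 0.41 and -5.67 ± 0.45. Gstm1, a glutathione transferase gene, rose from 0.163 ± 0.282 to 342 ± 42.6 TPM (log2 fold change 8.22 ± 0.31, adjusted p 4.13e-10). Wbp5 and Ngfrap1, small signalling adaptor genes, rose by 6.43 ± 0.58 and 5.96 ± 0.54. Card19, a mitochondrial protein gene, was at 65.1 ± 21.5 TPM and listed at 0 in IVF embryos. Tsix, the antisense partner of Xist, rose by 5.94 ± 0.66, and Xist, the RNA that silences an X chromosome, by 2.20 ± 0.33 to 4.52 ± 1.51 TPM. The embryo kit does not mark strand, so reads of Xist and Tsix cannot be assigned to either with certainty. Chaf1a had a log2 fold change of -0.09 ± 0.28 (adjusted p 0.806).

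Genes that mark the 2-cell stage were lower in TSC clones. Of 39 tested members, 35 fell and 0 rose (35 and 1 adjusted over the list alone, median log2 fold change -3.21, adjusted camera p 1.83e-25). That p was 0.114 with the estimated correlation. The summed TPM of the list was 9856 ± 867 in IVF embryos and 1276 ± 500 in TSC clones (SD, n = 3 each). Tcstv3, a gene of the 2-cell state (chromosome 13:120316862-120318261), fell from 681 ± 98.4 to 43.6 ± 6.63 TPM. Many members, such as Tcstv3 and the Zscan4 genes, have near-identical copies, so reads can be divided between them. Of 43 ribosome biogenesis genes, 29 fell and 1 rose (30 and 1, adjusted camera p 3.67e-16, 0.114 with the estimated correlation). The RNA helicase gene Ddx18 fell from 303 ± 27.3 to 56.7 ± 7.39 TPM. Of 41 maternal oocyte transcripts, 30 rose and 3 fell (30 and 3, adjusted camera p 0.00538, 0.334 with the estimated correlation). Bmp15, an oocyte growth factor gene, rose from 362 ± 56.8 to 1308 ± 197 TPM, while Dppa3, which protects maternal methylation, fell from 18391 ± 2583 to 4949 ± 724 TPM. The maternal list's adjusted camera p was 0.0931 with rescaled TPM.

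Trophoblast and imprinted genes were among those higher in TSC clones. Of 21 trophoblast stem cell factors, 14 rose and 1 fell (15 and 2 adjusted over the list alone, adjusted camera p 0.0252, 0.320 with the estimated correlation). The keratin gene Krt18 rose by 4.74 ± 0.40. Of 21 trophoblast differentiation genes, 13 rose (13, adjusted camera p 0.124), and Plet1, a surface protein gene of trophoblast progenitors, rose by 5.16 ± 0.53. Of 29 imprinted genes, 18 rose and 4 fell (23 and 4, adjusted camera p 0.0243, 0.114 with the estimated correlation). The translation regulator gene Impact rose from 3.92 ± 1.97 to 76.0 ± 14.1 TPM. Of 21 genes with non-canonical H3K27me3 imprints, 15 rose (18, adjusted camera p 0.00538, 0.188 with the estimated correlation), and Sfmbt2 rose from 0.207 ± 0.192 to 26.9 ± 8.40 TPM. Of 14 primitive endoderm markers, 9 rose and 1 fell (11 and 1, 0.0508). Of 9 fibroblast markers 5 rose (5, 0.194), and of 9 cumulus cell markers 4 rose and 1 fell (4 and 1, 0.560). Genes at least 4-fold higher in TSC than ESC, 359 of them tested, were higher in TSC clones than in IVF embryos for 89.7% of members, against 68.4% of the other genes (adjusted camera p 8.57e-05, 0.146 with the estimated correlation). For the 773 tested genes at least 4-fold higher in ESC that p was 0.859.

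Cell cycle lists were lower in TSC clones. Of 30 DNA replication genes, 12 fell and 5 rose (12 and 5 adjusted over the list alone, adjusted camera p 0.00366, 0.320 with the estimated correlation), and the replication helicase gene Gins2 fell by 2.69 ± 0.23 on the log2 scale. Of 22 mitotic genes, 9 fell and 4 rose (10 and 5, 6.67e-04, 0.216 with the estimated correlation), and the mitotic kinase gene Cdk1 fell from 831 ± 44.0 to 250 ± 68.5 TPM. Of 21 heat shock and unfolded protein response genes, 7 fell and 6 rose (7 and 6, 0.0252, 0.320 with the estimated correlation), with the chaperone gene Hsph1 falling from 108 ± 13.9 to 27.3 ± 7.57 TPM. The list of Xist with 4 Y-linked genes had 1 risen and 4 fallen members (1 and 4, 0.00366, 0.114 with the estimated correlation), and the translation factor gene Eif2s3y was at 32.8 ± 3.72 TPM in IVF embryos and listed at 0 in TSC clones. All 4 Y-linked genes were listed at 0 in every TSC clone library. Absence of a Y chromosome can thus not be told apart from lower expression.

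The other lists did not stand apart from other genes in TSC clones. H3K9 methylation factors had 6 risen and 7 fallen of 28 (5 and 7 adjusted over the list alone, adjusted camera p 0.0894), with the corepressor gene Trim28 at a log2 fold change of -1.32 ± 0.17 and the H3K9 methyltransferase gene Suv39h2 at 1.15 ± 0.18. Histone chaperones had 6 risen and 6 fallen of 21 (6 and 5, 0.162), among them Nasp, an H3 chaperone gene that fell by 1.55 ± 0.17. Histone H3 genes had 10 risen and 1 fallen of 13 (10 and 1, 0.246). The p53 targets had 10 and 4 of 23 (10 and 4, 0.783), and the Obox family 3 and 2 of 6 (3 and 2, 0.327). Interferon-stimulated genes had 5 and 2 of 17 (5 and 2, 0.535), and the chemokine gene Cxcl10 rose by 5.12 ± 0.51. Germline genes had 14 and 10 of 32 (14 and 10, 0.588), with the meiotic axis gene Sycp3 rising from 201 ± 18.8 to 1372 ± 60.6 TPM. Pluripotency factors had 8 and 7 of 24 (8 and 7, 0.375). Camera ranks a list against the other genes, and the median of all genes was above 0. So the direction of its test was down while the median, and for pluripotency factors also the mean, was above 0 for pluripotency factors, the Obox family and germline genes. For H3K9 methylation factors the median was -0.11 and the mean 0.00.

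shCont clones differed from IVF embryos in 6647 genes, 4599 higher and 2048 lower (limma, n = 3 per group). With rescaled TPM, 3346 were higher and 3058 lower. Of 39 2-cell stage genes, 21 were lower (21 adjusted over the list alone, median log2 fold change -1.21, adjusted camera p 4.22e-11), and of 43 ribosome biogenesis genes 22 were lower and 1 higher (22 and 1, 4.22e-11). Both had an adjusted p of 0.267 with the estimated correlation. Higher lists were non-canonical imprinted genes with 13 of 21 (13, 0.00958, 0.267 with the estimated correlation), trophoblast stem cell factors with 12 higher and 1 lower of 21 (12 and 1, 0.0184, 0.341) and trophoblast differentiation genes with 10 of 21 (11, 0.0473, 0.267). Mitotic genes had 7 lower and 3 higher of 22 (7 and 3, 0.0129, 0.341 with the estimated correlation), and DNA replication genes 8 and 5 of 30 (8 and 5, 0.0228, 0.456). Tcstv3 had a log2 fold change of -1.91 ± 0.18, while Obox3 had a log2 fold change of -0.84 ± 0.35 (adjusted p 0.0673, but 0.0427 without shCont clone replicate 2 and 0.0277 without shCont clone replicate 3). Without shCont clone replicate 1 it had one of -0.34 (adjusted p 0.358). Genes at least 4-fold higher in TSC than ESC were higher for 84.1% of members, against 66.3% of the other genes (adjusted camera p 0.00072, 0.146 with the estimated correlation), and for genes at least 4-fold higher in ESC that p was 0.56. Chaf1a had a log2 fold change of 0.17 ± 0.28 (adjusted p 0.649).

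**Figure D2:**
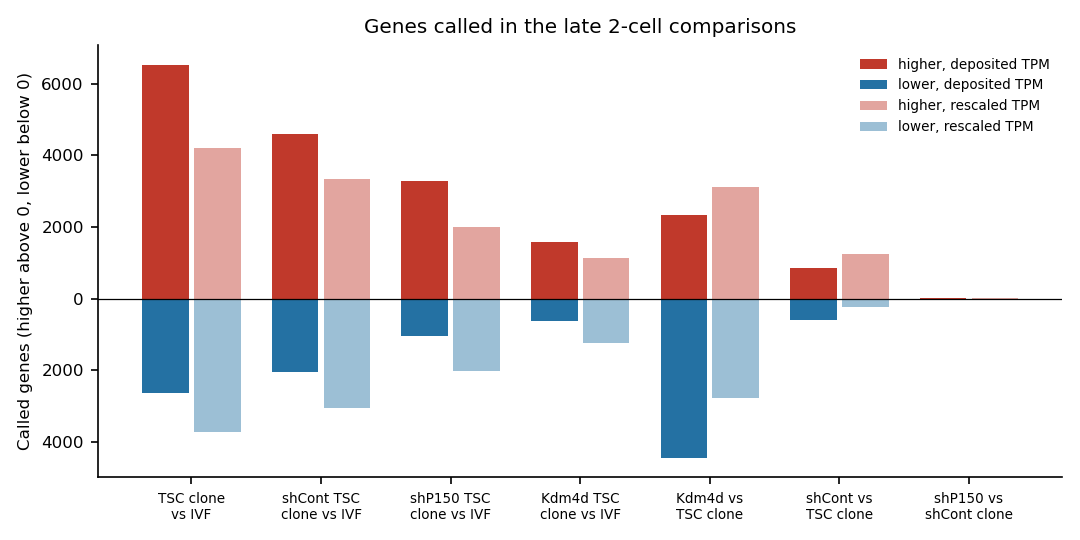
Number of called genes (vertical axis, limma, adjusted p under 0.05) in 7 embryo comparisons, with genes higher in the first-named group above 0 and lower ones below, from TPM as deposited (dark) and rescaled by median-of-ratios factors (light). TSC clones against IVF embryos had 6525 higher and 2648 lower genes, or 4216 and 3739 with rescaled TPM.

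Kdm4d clones differed from TSC clones in 6779 genes, 2335 higher and 4444 lower (limma, n = 3 per group). At least 2-fold changes numbered 1575 and 3020. With rescaled TPM, 3118 were higher and 2778 lower. Kdm4d, a demethylase of H3K9me3, rose by 10.98 ± 0.34 (SE, log2, adjusted p 4.46e-11). Obox3 rose to 512 ± 55.8 TPM (log2 fold change 5.85 ± 0.35, adjusted p 1.64e-07), BC147527 by 4.97 ± 0.41, Sva by 4.76 ± 0.61 and the histocompatibility gene H2-Q9 by 4.68 ± 0.60. The haemoglobin gene Hba-a2 fell by 5.83 ± 1.51, from 316 ± 104 to 23.1 ± 39.1 TPM (adjusted p 0.0066). Esx1, a placental homeobox gene, fell by 4.32 ± 0.37, and the developmental factor Sox11 fell by 4.11 ± 0.41. The actin regulator gene Tmsb15a fell by 3.81 ± 0.83 and Plet1 fell by 3.77 ± 0.53. Chaf1a had a log2 fold change of 0.44 ± 0.28 (adjusted p 0.217) and Xist one of -0.26 ± 0.33 (adjusted p 0.542).

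In Kdm4d clones, 33 of 39 2-cell stage genes rose and 1 fell (34 and 2 adjusted over the list alone, median log2 fold change 2.27, adjusted camera p 4.55e-19). That p was 0.269 with the estimated correlation. The summed TPM of the list was 4584 ± 111, and Tcstv3 rose by 2.01 ± 0.18. Ribosome biogenesis genes had 30 risen and 2 fallen of 43 (32 and 2, adjusted camera p 1.80e-14, 0.269 with the estimated correlation), with the nucleolar gene Mybbp1a at 52.1 ± 1.07 against 11.1 ± 1.95 TPM. Mitotic genes had 11 risen and 2 fallen of 22 (12 and 2, 3.84e-05), DNA replication genes 12 and 2 of 30 (12 and 2, 8.40e-04) and heat shock genes 9 and 3 of 21 (9 and 4, 0.00203). With the estimated correlation these adjusted p were 0.269, 0.342 and 0.269. Cdk1 rose to 731 ± 35.3 TPM, the mitotic activator gene Cdc20 from 180 ± 71.7 to 962 ± 331, the replication licensing gene Cdt1 from 23.9 ± 6.34 to 67.6 ± 5.99 and the chaperone gene Hspa8 from 107 ± 13.3 to 330 ± 46.1. Maternal oocyte transcripts had 3 risen and 28 fallen of 41 (3 and 29, adjusted camera p 8.40e-04, 0.342 with the estimated correlation), with Bmp15 falling to 474 ± 66.3 and Dppa3 rising to 12940 ± 352 TPM.

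Trophoblast stem cell factors had 2 risen and 14 fallen of 21 in Kdm4d clones (3 and 14 adjusted over the list alone, adjusted camera p 0.0503), and the keratin gene Krt19 fell from 25.3 ± 14.6 to 1.79 ± 0.927 TPM. Pluripotency factors had 8 and 4 of 24 (9 and 4, 0.0560), with the 2-cell and pluripotency gene Dppa2 rising from 139 ± 41.7 to 615 ± 123 TPM. Imprinted genes had 4 and 13 of 29 (4 and 15, 0.234), non-canonical imprinted genes 1 and 9 of 21 (1 and 9, 0.143) and histone H3 genes 1 and 8 of 13 (1 and 8, 0.118). Impact fell to 17.2 ± 2.75 TPM and Sfmbt2 to 4.37 ± 2.02 TPM. Suv39h2 fell by 1.22 ± 0.18, and the H3.3 gene H3f3a rose by 0.94 ± 0.11.

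**Figure D3:**
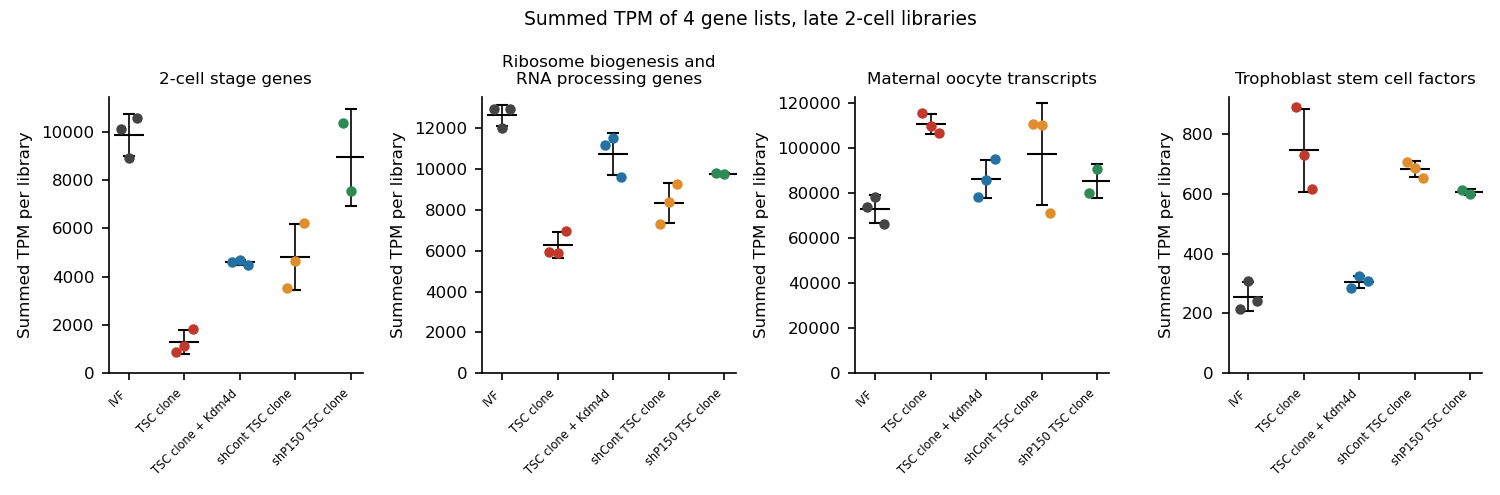
Summed TPM per library (vertical axis, linear) of 4 gene lists in the embryo groups, with a point per library and bars at the group mean ± SD (n = 3, shP150 clones 2). The 2-cell stage genes had means of 9856 in IVF embryos, 1276 in TSC clones and 4584 in Kdm4d clones.

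Clones from shP150 donors differed from those of shCont donors in 16 of 16035 genes, 6 higher and 10 lower in shP150 clones (limma, n = 2 and 3). These were 13 and 3 without shCont clone replicate 3, 9 and 8 without shCont clone replicate 2, and 24 and 11 without a filter. All 16 differed by at least 2-fold, and 2013 genes had an unadjusted p under 0.05. Tcstv3 had the smallest p and was at 524 ± 113 TPM in shP150 clones and 180 ± 25.8 in shCont clones (log2 fold change 1.53 ± 0.20, adjusted p 0.0181). The olfactory receptor gene Olfr450 was higher by 3.17 ± 0.46, the immunity GTPase gene Irgm1 by 2.99 ± 0.49 and the RNA-binding protein gene Stau1 by 1.36 ± 0.22. The log2 fold change was -2.57 ± 0.39 for the endoplasmic reticulum gene Rtn1 and -1.90 ± 0.32 for the respiratory chain gene Ndufa8. It was -1.81 ± 0.30 for the unassigned transcript BC023829 and -1.68 ± 0.28 for the sperm protein gene Spa17. The LIM-domain gene Fhl1 was at 7.96 ± 4.80 TPM in shCont clones and listed at 0 in shP150 clones. Each of these 9 genes lost its call when some single libraries were left out, with an adjusted p between 0.0531 and 0.209 in those fits. Without shCont clone replicate 1, limma called 0 genes, with 1617 at an unadjusted p under 0.05, and Tcstv3 had an adjusted p of 0.0655. Without shP150 clone replicate 1 it called 8 genes, with Tcstv3 at 0.0894, and without shP150 clone replicate 2 it called 3. In a fit of these groups alone it called 0 of 14422 genes, with 1517 at an unadjusted p under 0.05. With the replicate number as a block it also called 0, with 2017 at an unadjusted p under 0.05.

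As a list, 2-cell stage genes were higher in shP150 than in shCont clones by camera (adjusted p 3.04e-09), a call that was lost with the estimated correlation (adjusted p 0.803). The median log2 fold change was 0.76, and 1 of 39 members rose, or 6 adjusted over the list alone. The summed TPM of the list was 8934 ± 1994 in shP150 clones (n = 2) and 4796 ± 1361 in shCont clones (n = 3). Ribosome biogenesis genes had a median of 0.19 with 0 members called, or 2 adjusted over the list alone (adjusted camera p 3.73e-04, 0.803 with the estimated correlation). Germline genes had a median of -0.32 with 0 called, or 3 fallen adjusted over the list alone (adjusted camera p 1.69e-04, 0.320 with the estimated correlation). Of 28 H3K9 methylation factors 0 were called, or 3 risen adjusted over the list alone (adjusted camera p 0.121), and the H3K9 methyltransferase gene Setdb1 had a log2 fold change of 1.18 ± 0.27 (adjusted p 0.102). Genes risen or fallen in shP150 TSC did not stand apart in shP150 clones, with adjusted camera p of 0.873 and 0.859. Xist had a log2 fold change of 0.17 ± 0.37 (adjusted p 0.892).

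**Figure D4:**
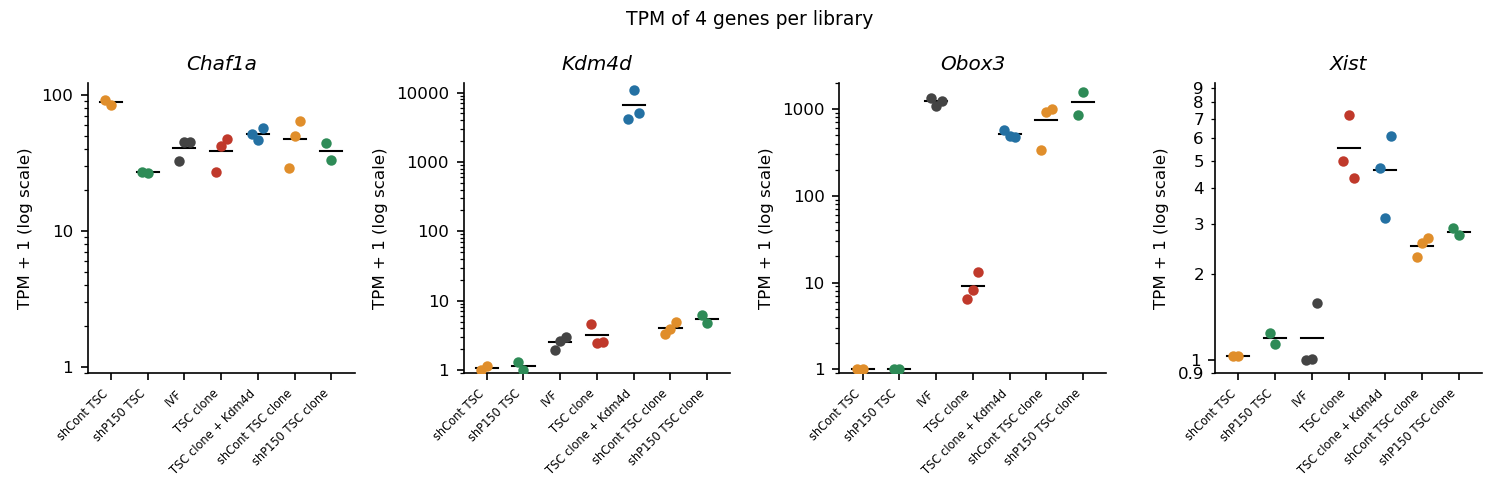
TPM + 1 (vertical axis, log scale) of Chaf1a, Kdm4d, Obox3 and Xist in the hairpin TSC and the embryos, with a point per library and a bar at the group mean. Obox3 had a mean TPM of 1221 in IVF embryos, 8.23 in TSC clones and 512 in Kdm4d clones.

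Whether either treatment moved genes towards IVF embryos was tested on gene sets taken from libraries outside each contrast. Of the 2048 genes lower in shCont clones than in IVF embryos, 89.2% were higher in Kdm4d than in TSC clones, against 26.9% of the other genes (median log2 fold change 0.92, adjusted camera p 5.24e-72, 0.00195 with the estimated correlation). Of the 4599 genes higher in shCont clones, 88.4% were lower in Kdm4d clones, against 55.2% of the other genes (median -0.91, adjusted camera p 1.95e-24, 0.00195 with the estimated correlation). Of the 2648 genes lower in TSC clones than in IVF embryos, 82.3% were higher in shP150 than in shCont clones, against 45% of the other genes (median 0.34, adjusted camera p 6.39e-23, 0.0319 with the estimated correlation). Of the 6525 genes higher in TSC clones, 65.7% were lower in shP150 clones, against 36.4% of the other genes (median -0.16, adjusted camera p 1.09e-13, 0.0139 with the estimated correlation). With fry, which tests a set against no change, the unadjusted p of this last set was 0.0588. Those of the sets before it were 3.42e-06, 2.54e-07 and 0.0230 in order. In the sets of shP150 clones, 3 genes were called higher and 0 lower in the first, and 7 lower and 1 higher in the second. In those of Kdm4d clones, 1294 were called higher and 28 lower in the first, and 2576 lower and 83 higher in the second. None of these set tests was repeated with a library left out. Across genes, the Kdm4d effect correlated with that of the P150 hairpin (r 0.445). Setting shCont clone replicates 1 and 2 against the rest gave an r of similar size, -0.439. Movement of shP150 clones towards IVF embryos thus cannot be told apart from the order of single libraries along the axis of cloning.

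The treated clones still differed from IVF embryos. Kdm4d clones had 1582 genes higher and 624 lower (limma, n = 3 per group), or 1142 and 1245 with rescaled TPM. The count of 2206 fell to 1409 without IVF replicate 1, 1423 without IVF replicate 3, 1454 without Kdm4d clone replicate 1 and 1453 without Kdm4d clone replicate 3. Tcstv3 had a log2 fold change of -1.92 ± 0.18 and Obox3 one of -1.25 ± 0.35, with an adjusted p of 0.0275 that rose to 0.0911 without IVF replicate 1, 0.0773 without IVF replicate 3, and 0.0543, 0.0767 and 0.0866 without Kdm4d clone replicates 1, 2 and 3. shP150 clones had 3293 genes higher and 1049 lower (n = 2 and 3), or 2007 and 2014 with rescaled TPM. That count of 4342 fell to 2094 without shP150 clone replicate 1 and to 2765 without shP150 clone replicate 2. Tcstv3 had a log2 fold change of -0.38 ± 0.20 (adjusted p 0.161) and Obox3 one of -0.08 ± 0.39 (adjusted p 0.906), with a log2 fold change of 0.35 without shP150 clone replicate 1 and -0.51 without replicate 2. That of Tcstv3 was -0.61 without shP150 clone replicate 1 and -0.16 without replicate 2, and was not called in either. Chaf1a had log2 fold changes of 0.36 (adjusted p 0.478) in Kdm4d clones and -0.07 (adjusted p 0.902) in shP150 clones. Kdm4d was higher in shP150 clones than in IVF embryos by 1.13 ± 0.38 (adjusted p 0.0401). That p was 0.121 without IVF replicate 1, 0.0647 without IVF replicate 2, and 0.222 and 0.0805 without shP150 clone replicates 1 and 2.

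The effect of injected Kdm4d and that of the P150 hairpin in the donor were compared in the same fit. Their difference was called in 1100 genes, 458 with the higher value for Kdm4d and 642 with the lower, and with rescaled TPM these were 972 and 220. For Obox3 the difference was 5.09 ± 0.53 (SE, log2, adjusted p 4.14e-04), and for Tcstv3 0.48 ± 0.26 (adjusted p 0.257). Obox3 was at 753 TPM in shCont clones and 8.23 in TSC clones, so the treatments started from unequal levels. The count fell to 180 without shP150 clone replicate 1 and 273 without replicate 2, to 264 and 255 without Kdm4d clone replicate 1 or 2, to 456 and 695 without TSC clone replicate 1 or 2, and to 684 and 511 without shCont clone replicate 2 or 3. More genes had the higher value for Kdm4d without shP150 clone replicate 1 (105 against 75), Kdm4d clone replicate 2 (138 against 117) or TSC clone replicate 1 (238 against 218).

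The clone groups without injected Kdm4d or the P150 hairpin differed from each other. shCont clones had 842 genes higher and 607 lower than TSC clones (limma, n = 3 per group), and 1248 and 241 with rescaled TPM. The count of 1449 fell to 677 without shCont clone replicate 3, 701 without TSC clone replicate 1, 880 without shCont clone replicate 2 and 305 in a fit of these groups alone. Of 39 2-cell stage genes 32 were higher in shCont clones (33 adjusted over the list alone, median 2.01, adjusted camera p 3.60e-35, 0.0630 with the estimated correlation). Obox3 was at 753 TPM in shCont clones and higher by 6.26 ± 0.35. Ribosome biogenesis genes had 9 higher of 43 (12, 1.47e-10, 0.244 with the estimated correlation), heat shock genes 2 of 21 (6, 7.41e-04, 0.244) and mitotic genes 4 of 22 (7 higher and 2 lower, 0.00202, 0.318). Maternal oocyte transcripts had 6 lower of 41 (1 higher and 11 lower, 3.19e-04, 0.361 with the estimated correlation). Their summed TPM was 70987 in shCont clone replicate 3. In shCont clone replicates 1 and 2 it was 110640 and 110020, within the 106730 to 115310 of TSC clones. Xist with Y-linked genes had 3 higher of 5 (4 higher and 1 lower, 1.65e-06), and this call held with the estimated correlation (0.0111). Chaf1a had a log2 fold change of 0.26 (adjusted p 0.598) and Xist one of -1.10 ± 0.33 (adjusted p 0.0511). The TSC and the hairpin TSC are labelled with different crosses, while the labels of all embryos give the same strain and do not name the donor line.

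Genes on chromosome X, 607 in the embryo fit, were lower relative to other genes in 3 of 9 comparisons tested. Against IVF embryos, the adjusted camera p was 0.000802 in Kdm4d clones, 0.000589 in shP150 clones and 0.0282 in shCont clones. With the estimated correlation these were 0.486, 0.486 and 0.557, and with rescaled TPM that of shCont clones was 0.0933. It was 0.111 in TSC clones against IVF embryos. The labels do not give the sex of the embryos or donor lines. Y-linked genes had a summed TPM of 49.8 to 60.0 in IVF embryos and 73.3 to 78.5 in shCont clones. It was 78.8 and 87.8 in shP150 clones, and 0 in Kdm4d clones. Sex may thus differ between these groups, and its effect on X-linked genes cannot be told apart from that of cloning. Values of Xist may include reads of Tsix, since the embryo kit does not mark strand. Xist was higher than in IVF embryos by 1.94 ± 0.33 in Kdm4d clones (adjusted p 0.00162), 1.10 ± 0.33 in shCont clones (0.0154) and 1.27 ± 0.37 in shP150 clones (0.0210). The call in shCont clones was lost without IVF replicate 1 (0.0581) or 2 (0.0553). That in shP150 clones was lost without IVF replicate 1 (0.0648), IVF replicate 2 (0.0593), shP150 clone replicate 1 (0.109) or shP150 clone replicate 2 (0.0777).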

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

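Of the tests of explanations in this part, the first test of admixed pluripotent cells was set before its result was seen, and the others and the counts of other splits were chosen afterwards.

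TSC clones and shCont clones differed from IVF embryos to unequal degrees. Each group was compared with the same IVF embryos, and the test of the difference, shCont clones against TSC clones, called 1449 genes. That count was 677 without shCont clone replicate 3, 701 without TSC clone replicate 1 and 880 without shCont clone replicate 2, and 305 in a fit of these groups alone. These groups were the controls of the treatments, which thus started from unequal levels. The effects of Kdm4d and of the P150 hairpin in the donor also differed, in 1100 genes by a test of the difference, and in 180 to 1503 genes without any single library, lowest without shP150 clone replicate 1. Other low counts were 273 without shP150 clone replicate 2, 255 and 264 without Kdm4d clone replicate 2 or 1, 456 and 695 without TSC clone replicate 1 or 2, and 511 and 684 without shCont clone replicate 3 or 2.

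The lower 2-cell stage genes of TSC clones (median log2 fold change -3.21) do not rest on scaling, since their median was -3.72 with rescaled TPM. Reads divided between near-identical copies do not account for all of the fall, but 6 genes chosen afterwards cannot exclude that they add to it. The 6 members chosen as lacking such copies had a median of -2.63, and 4 of them fell, while Zfp750 (0.60) and Usp26 (1.01) were not called. Slower development of the clones stays open: the maternal list had a median of 0.862, against 0.587 for all genes. Its call was lost with rescaled TPM and with the estimated correlation. Slower loss of maternal RNA would give a higher median, and failed genome activation would as well. These cannot be told apart without a time course.

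In shP150 TSC, 1114 genes rose and 416 fell (1295 and 1061 without shP150 replicate 1, 669 and 122 without shCont replicate 1, 728 and 218 without shCont replicate 2), 6 of 16 tested fibroblast markers among the risen ones (adjusted camera p 8.46e-05, 0.414 with the estimated correlation). Feeder fibroblasts are argued against as their source, since the TPM rise of the collagen genes that abound in fibroblasts (Col1a1, Col1a2 and Col3a1) averaged 0.0142 of that of these 6 markers, and at most 0.0239 in any pair of libraries. Admixed pluripotent cells were tested by the rise that a share set by Pou5f1, 0.509% of ESC RNA, would bring to 45 genes abundant in ESC, and this test did not decide (median of observed over expected rise 0.43). A second test, on the 18 of these genes whose level in shCont TSC was below the expected rise, gave a median of 0.0137 and argues against such cells as the source of Pou5f1. Loss of P150 itself stays a hypothesis, and effects of the hairpin sequence or of the line were not tested.

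The 2-cell stage genes were higher in shCont than in TSC clones (median 2.01). A swap of some but not all libraries is argued against. In the summed TPM of the Y-linked genes, 0 of the 6 libraries were out of place, with 0 in each TSC clone library and 73.3 to 78.5 in shCont clones. An exchange of the whole groups had no test of its own. It is argued against by that sum in the treated clones, 0 in each Kdm4d clone library and 78.8 and 87.8 in shP150 clones. This holds if Kdm4d clones shared the donor line of TSC clones, and shP150 clones that of shCont clones. With rescaled TPM the median was 2.16. Genes on the sex chromosomes made up 2.83% of the 1380 called genes with a known chromosome, against 4.04% of those tested. Lentiviral hairpin and expression of Y-linked genes differ together between these groups, and the line and strain of the donor and the day of the experiment, which the labels do not give for embryos, may differ as well, so these cannot be told apart.

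Other splits of the 6 libraries of a comparison were counted. There are 10, too few for a share under 0.05. TSC clones against IVF embryos gave 9173 called genes and at most 0 in another split, by limma, Kdm4d against TSC clones 6779 and 0, shCont clones against IVF embryos 6647 and 0, Kdm4d clones against IVF embryos 2206 and 1, and shCont against TSC clones 1449 and 1. In each, 1 of the 10 splits, the real one, gave as many.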

How the results depend on the processing

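All alternatives were set before their results were seen, and the cause of a difference was not tested unless stated.

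For shP150 against shCont TSC, the main count of 1530 called genes was 1086 with DESeq2 (1040 shared), 1535 with RLE size factors, 2043 without a filter and 444 with limma on TPM (413 shared). It ranged from 791 (without shCont replicate 1) to 2356 (without shP150 replicate 1) when a library was left out. For TSC against ESC, the count of 3675 ranged from 1875 (without TSC replicate 2) to 3987. For TSC clones against IVF embryos and Kdm4d against TSC clones, no alternative moved the count by more than 1.5 times, nor for shCont clones against IVF embryos.

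For shP150 against shCont clones, the count of 16 was 35 without a filter and 0 in a fit of the compared groups alone (limma, 1517 genes at an unadjusted p under 0.05). It ranged from 0 (without shCont clone replicate 1, 1617 at an unadjusted p under 0.05) to 17 when a library was left out. Kdm4d clones against IVF embryos ranged from 1409 (without IVF replicate 1) to 1799, shP150 clones against IVF embryos from 2094 (without shP150 clone replicate 1) to 3731, and shCont against TSC clones from 677 (without shCont clone replicate 3) to 1639. The last was 305 in a fit of these groups alone. The difference of the Kdm4d and shP150 effects ranged from 180 (without shP150 clone replicate 1) to 1503, and was 718 in a fit of those groups alone. Fewer libraries leave fewer residual degrees of freedom in the fits of some groups only.

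Whether replicate numbers paired the libraries could not be decided, since each comparison held so few of them. In none of the 3 main embryo comparisons, the only ones of embryos so examined, were all same-numbered libraries' deviations correlated above 0.1. Those of TSC and ESC (0.143) and of the hairpin TSC (0.0861) rest on 2 libraries per group. With the replicate number as a block, shP150 against shCont clones had 0 called genes (limma, 2017 at an unadjusted p under 0.05), the difference of the effects 535 and shP150 against shCont TSC 1986. The other counts stayed within 1.5 times: 4180 for TSC against ESC, 8967 for TSC clones, 6461 for shCont clones, 2069 for Kdm4d clones and 3770 for shP150 clones against IVF embryos, 6604 for Kdm4d and 1214 for shCont against TSC clones. All fixed-list calls of the 5 main comparisons were kept with the block.

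With the estimated correlation, all fixed-list calls of the 5 main comparisons were lost (6 in shP150 TSC, 8 in TSC against ESC, 10 in TSC clones, 6 in Kdm4d and 3 in shP150 clones). So were those of genes higher in TSC than ESC in TSC clones (0.146) and shCont clones (0.146), and of X-linked genes against IVF embryos in shCont (0.557), Kdm4d (0.486) and shP150 clones (0.486). The 4 sets that tested movement towards IVF embryos kept their calls. The lost calls need not reflect correlated genes, since camera here uses only the residual degrees of freedom, 2 in the ESC and TSC fit. For ribosome biogenesis genes in shP150 TSC the estimated correlation was -0.0200, and the call was still lost. In other lists it was higher, such as 0.739 for 2-cell stage genes in TSC against ESC. With rescaled TPM, the X-linked call in shCont clones (0.0933) and the maternal list in TSC clones (0.0931) were lost, and the other calls of fixed lists in the main comparisons of TPM were kept. A pseudocount of 0.1 lost none of these. In shP150 against shCont clones, 6 of 9 named calls were kept with that pseudocount.

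The log2 fold change of Chaf1a between embryo groups, which was not called, changed sign in some fits. It ranged from -0.25 (without TSC clone replicate 3) to 0.15 (without TSC clone replicate 1) in TSC clones against IVF embryos. In shP150 against shCont clones it ranged from -0.55 to 0.0118 (without shCont clone replicates 1 and 3), in shCont clones against IVF embryos from -0.0776 to 0.49 (without shCont clone replicates 3 and 1), and in shP150 clones against IVF embryos from -0.27 to 0.14 (without shP150 clone replicates 1 and 2). It was -0.17 in shCont clones with rescaled TPM and, with the replicate block, 0.0778 in shP150 clones.

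Of the calls of named genes, 165 of 205 were kept when a library was left out in shP150 TSC, 176 of 196 in TSC against ESC, 563 of 570 in TSC clones, 514 of 516 in Kdm4d clones and 13 of 45 in shP150 clones. For shP150 TSC, 46 of 52 were kept with DESeq2 and 25 of 48 with limma on TPM. No named call changed sign in these fits. Unknown depth of the TPM libraries leaves the counting error of low genes unknown.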

Other observations

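The tests of chromosome neighbours and of the ESC and TSC programmes were set before their results were seen, and the correlation of effects was chosen afterwards. The genes named in this part were chosen after their values were seen.

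Some genes outside the lists rose in shP150 TSC (edgeR, n = 2 per group). The neurofilament genes Nefl and Nefh rose by 3.35 ± 0.16 and 3.26 ± 0.25 (SE, log2), and Nefm by 2.57 ± 0.18. Dpysl3, which guides growing axons, rose by 2.70 ± 0.12, the neurotrophin receptor gene Ntrk2 by 6.10 ± 0.38 and the cadherin gene Cdh2 by 2.98 ± 0.19. Ntrk2 did not pass the filters of the naming rule, a mean TPM of at least 5 in the higher group and no overlap of libraries. The linker histone gene Hist1h1c rose from 11.2 ± 0.939 to 117 ± 26.3 TPM, H1f0 by 1.70 ± 0.13 and H1fx by 1.92 ± 0.15. Nefl was at 57.5 ± 12.5 TPM in TSC of the other cross and 7.66 ± 0.619 in shCont TSC.

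Several genes with large differences between shCont and TSC clones had higher values in both groups from hairpin donors, or in both without. The microRNA gene Mir692-3 had a mean TPM of 539 in shCont clones and 429 in shP150 clones, but 5.20 in TSC clones, 1.56 in Kdm4d clones and 0.943 in IVF embryos. The embryo kit amplifies full-length cDNA and does not mark strand, so these reads may come from transcripts that overlap the gene. The neuropeptide gene Npy was at 103 and 55.9 TPM in shCont and shP150 clones and at 3.53 in TSC clones, 0.267 in Kdm4d clones and 0.144 in IVF embryos. Kdm4c, a relative of Kdm4d, was at 108 and 147 TPM in shCont and shP150 clones and 29.0 in TSC clones, 31.6 in Kdm4d clones and 47.4 in IVF embryos. Wtap, a gene of the RNA methylation complex, was at 335 and 475 TPM, against 80.8, 137 and 165 in the same order. H19 was at 14.3 TPM in TSC clones and 4.82 in Kdm4d clones, and listed at 0 in the other embryo groups.

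Y-linked genes were listed at 0 in all 6 libraries of TSC clones and Kdm4d clones, while their summed TPM was 49.8 to 60.0 in IVF embryos, 73.3 to 78.5 in shCont clones and 78.8 and 87.8 in shP150 clones. The sequenced TSC expressed them, with Eif2s3y at 63.7 ± 2.38 TPM and Ddx3y at 37.2 ± 2.26. The TSC that gave the nuclei of these clones are not named in the labels. The values at 0 in all 6 libraries argue against the sequenced line, with its Y-linked expression, as their donor.

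Behind the tests of other cells in shP150 TSC stood these values. Col1a1 had 17 and 37 counts in shP150 TSC and 14 and 21 in shCont TSC (log2 fold change 0.73 ± 0.40, edgeR adjusted p 0.275). Col1a2 and Col3a1 had at most 2 counts in any library, too few to be tested, so the deciding value was changed from the median fold change of these genes to the number called, and then to the ratio of TPM rises, after each was seen. The mean TPM rise was 0.0903 for the 3 collagen genes and 6.38 for the 6 called markers. Of the 23 fibroblast markers, 7 had TPM of at least 1 in shCont TSC and 1 stood on another list. Per the labels, the lines had been adapted to growth without feeders. Of the 45 genes abundant in ESC, 16 rose by at least the expected amount and 20 by less than 0.25 of it, and of the 18 low in shCont TSC 14 did the latter.

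Genes at least 4-fold higher in ESC than TSC were tested in shP150 TSC. Of 605 tested, 163 rose and 2 fell, with a median log2 fold change of 0.422 (camera p 1.24e-15, 0.0482 with the estimated correlation). The 458 tested genes at least 4-fold higher in TSC had a median of -0.016, with 46 risen and 66 fallen (camera p 0.0816, 0.342 with the estimated correlation), which decided nothing. The 2 lines differ in cross, and the ESC values come from another table. No set matched for expression level was tested, and genes low in TSC have more room to rise than to fall. The list of pluripotency factors did not stand apart in shP150 TSC, with 5 risen and 3 fallen of 18 (adjusted camera p 0.483). So the first result is a hypothesis that P150 loss may raise genes that are lower in TSC than in ESC.

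Neighbouring genes changed together slightly more often than in 1000 shuffles within 20 expression bins. Risen genes of shP150 TSC made 115 adjacent pairs against a mean of 84.5, a ratio of 1.36 (p 0.002). Fallen genes of TSC clones made 545 pairs against 419.5, a ratio of 1.3 (p 0.001, the smallest that these shuffles can give). Both ratios were below the 1.5 set beforehand for a chromosomal pattern and above the 1.2 set for none, so the test was undecided.

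The effects of Kdm4d and of the P150 hairpin in the donor correlated across genes (Pearson's r 0.445), although they share no library and genes are not independent replicates. The 10 splits of the 5 hairpin clone libraries are too few for a share under 0.05, and r ranged from -0.439 to 0.302 in the others, the former with shCont clone replicates 1 and 2 set against the rest. Both treatments may move the same genes, but with these splits that cannot be told apart from the order of the libraries along the axis of cloning.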
